A study of Homo sapiens with 8 samples.

How the data were processed

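Messenger RNA was measured in 8 libraries of H7 embryonic stem cell-derived cells: untreated cells and cells given bleomycin at 24, 240 or 480 µg/ml, 2 libraries each. Per the labels, 500 µl of bleomycin lay on the apical side for 24 hours, and TruSeq stranded mRNA libraries were made from 1 µg of total RNA. The differentiation took 6 days to definitive endoderm, 4 days to anterior foregut, 4 days to ventralized foregut and 7 days to lung progenitors, 21 days in all, before culture on inserts.

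The deposited tables give 1 value per gene symbol and library in 3 units: whole-number read counts, TPM (length-scaled values with a common total) and FPKM (fragments per kilobase of gene, scaled to library size). The authors named Trimmomatic, HISAT2, Bowtie2, StringTie and the build GRCh38, without versions, annotation release or the strand counted. The deposited counts carry no normalization, the deposited TPM values sum to the same total in every library, and the deposited FPKM values are proportional to TPM within a library. The count table had 46427 symbols, of which 42656 matched RefSeq symbols of GRCh38.p14, and coordinates are from that annotation. Counts were used for all tests, TPM for 1 alternative and FPKM only to estimate gene lengths. All columns were used.

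Total counts ran from 53431800 to 67716000 per library. A count of 0 allows up to 3 counts, which is 0.0443 to 0.0561 CPM across libraries.

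Groups were compared by edgeR 4.0.16 in R 4.3.3 with TMM factors, a quasi-likelihood fit over all 8 libraries with group as the only term, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05 and no threshold on the fold change. The filter (filterByExpr, at least 10 counts and 15 in total) left 18303 genes. The fit had 4 residual and 4.98 prior degrees of freedom and a common dispersion of 0.0226, a biological coefficient of variation of 0.15. The SE of a log2 fold change is its size divided by the square root of the F statistic. Each dose was compared with untreated cells, and the doses with each other, which makes 6 comparisons. Overlap between doses was set beside independent lists and 20 simulations with no effect.

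Of the 30 gene lists, each from textbook knowledge, those with at least 5 tested members were tested by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. They cover p53 targets, G2 phase and mitosis, DNA replication, homologous recombination, histones, type 2 and type 1 alveolar cells, lung progenitors, transitional and basaloid cells, EMT and matrix, epithelial junctions and the TGF-beta response. The rest cover secretory and inflammatory genes, interferon, unfolded protein, NRF2, metal, sterol and lipid, heat shock and immediate early responses, and ciliated, secretory, basal, neuroendocrine, hepatic, intestinal, mesenchymal, endothelial, pluripotent and neural cells. Across lists, 20 genes are on more than 1, including 5 mesenchymal genes that the EMT and matrix list also holds. camera with an estimated correlation and fry were run beside it; fry tests whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes.

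The tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule names, for each dose, the 8 highest and 8 lowest log2 fold changes among called genes with an average log2 CPM of at least 3 and both treated libraries beyond both untreated ones, and 5 of each between doses. It further names up to 4 members of each list by smallest p, the member with the smallest p that moves the other way, and a fixed set that includes CDKN1A, MDM2, GDF15, MKI67, SFTPC, SFTPB, NKX2-1, KRT8, KRT17, COL1A1, FN1, ACTA2, CDH1, VIM, TGFB1, IL6 and CXCL8. Symbols of uncertain identity were passed over, and not every gene that the rule names is given in the text.

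Alternatives were DESeq2 1.42.0 with its own size factors and filter, RLE factors, no filter on low counts, a stricter filter (at least 50 counts in at least 2 libraries), only the libraries of the 2 groups compared, replicate number as a block, limma on log2(TPM + 1) and each library left out in turn. DESeq2 and limma on TPM change the test and the scaling together. A fit without ribosomal RNA, mitochondrial and AFP counts was added after the data were seen. The method was tested on simulated data of 17921 genes. In each run 65 to 67 genes per fold carried a planted change, and the rest carried none. At 24 µg/ml edgeR recovered 9.2%, 49.3% and 86.4% of genes changed 1.5-, 2- and 4-fold with 1 false call. At 480 µg/ml it recovered 18.2%, 65.2% and 83.3% with 7. Both runs drew every group with the same spread for a gene, while the real libraries of 480 µg/ml lay further apart. The recovery rates therefore do not compare the sensitivity of the doses. They may also overstate it at 24 µg/ml, where 605 real genes had unadjusted p under 0.05 and chance alone would give 915. Genes with overlapping neighbours on the other strand, such as ACTA2 and FAS, have uncertain counts, as do similar genes, such as metallothioneins and histones. The strand and the handling of shared reads are not stated. Exon overlap of ACTA2 and FAS was taken from GENCODE release 29, and figures were drawn with matplotlib 3.10.9.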

Results

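RNA was sequenced from human H7 embryonic stem cells that had been turned, step by step, into cells named in the labels as differentiated type 2 alveolar cells, the surfactant-making cells of the lung alveolus. They passed through endoderm, foregut and lung progenitor stages over 21 days, then spent 3 days submerged on inserts and 7 days at an air-liquid interface. Bleomycin, a drug that breaks DNA and provokes lung fibrosis in animals, was laid on the apical side for 24 hours at 24, 240 or 480 µg/ml, and 1 group was left untreated. The labels give a bleomycin stock of 10 µg/ml, which is below each of the 3 doses. Each of the 4 groups had 2 libraries, and the labels do not say whether the 2 were separate cultures. Total counts per library ran from 53431800 to 67716000. The question stated for the series is which fibrosis-related genes such cells express after bleomycin. Levels are means of counts scaled to a common library size (CPM) ± SD over n = 2 libraries, and a value ± error without a unit is a log2 fold change ± SE against untreated cells unless another group is named. Adjusted p comes from edgeR over 18303 genes, and only genes with adjusted p under 0.05 are said to be called, to rise or to fall. These p-values measure the spread between these libraries, which may be technical.

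The untreated cells expressed epithelial genes at high levels and markers of alveolar cells at levels that differed widely. Of type 2 cell markers 19 of 25, and of type 1 cell markers 17 of 18, passed the filter on low counts. Those that did not pass included the surfactant protein genes SFTPA1 and SFTPA2, with at most 2 and 7 counts in a library. The type 1 marker gene AQP5 had at most 4. Passing the filter shows that a gene was counted, not that the cells were type 2 cells. CDH1, which encodes E-cadherin of cell junctions, stood at 1059 ± 1.91 CPM, and the keratin gene KRT8 at 2021 ± 173 CPM. SFTPB, a surfactant protein gene, had 15.9 ± 1.38 CPM, the lung transcription factor gene NKX2-1 had 0.923 ± 0.136 CPM and the surfactant lipid transporter gene ABCA3 had 13.1 ± 1.58 CPM. The surfactant lipid enzyme gene LPCAT1 stood at 118 ± 2.39 CPM, the phosphate transporter gene SLC34A2 at 14.7 ± 0.901 CPM and the type 1 marker gene GPRC5A at 337 ± 7.48 CPM. SFTPC, the surfactant gene most specific to type 2 cells, had 5 counts in 24 µg/ml replicate 2, 7 counts in 480 µg/ml replicate 1 and 0 in the other 6 libraries, where 3 counts would be at most 0.0561 CPM. Such floors cover counting error only. IL6, an inflammatory cytokine gene, had 0 counts in all 8 libraries, and the basal keratin gene KRT17 had at most 3. The hepatic gene AFP, named after its values were seen, took 4.37 ± 0.189% of counts in untreated cells, and the intestinal transcription factor gene CDX2 stood at 198 ± 11.1 CPM. FN1, the gene of the matrix protein fibronectin, had 11845 ± 943 CPM.

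Gene expression differed from untreated cells at 240 and 480 µg/ml. No single gene was called at 24 µg/ml by edgeR over all 8 libraries with the filter on low counts. The first principal component held 49.9% of the variance and separated the 240 and 480 µg/ml libraries from the others, and the second held 12.1% and set the 2 libraries of 480 µg/ml apart. The SD of the log2 ratio between the 2 libraries of a group was 0.637 at 480 µg/ml and between 0.502 and 0.520 in the other groups. That SD gives each gene the same weight. Set against counting error, where highly counted genes weigh more, the difference between the 2 libraries stood further apart. Its chi-square per degree of freedom was 18.55 in untreated cells and 51.3, 21.64 and 162.43 at 24, 240 and 480 µg/ml. The number of genes with at least 1 count was 21948 ± 225 in untreated cells and 24054 ± 626 at 480 µg/ml. Mitochondrially encoded genes took 1.56 ± 0.0431%, 1.28 ± 0.322%, 1.89 ± 0.226% and 2.35 ± 0.934% of counts in untreated cells and at 24, 240 and 480 µg/ml. Ribosomal RNA took 1.21% in 480 µg/ml replicate 1, 3.30% in 480 µg/ml replicate 2, 1.57% and 1.63% in the libraries of 240 µg/ml, 2.93% and 1.78% in those of 24 µg/ml and 1.67% and 1.32% in the untreated libraries. Without the counts of both and of AFP, an alternative chosen after the data were seen, the genes higher and lower numbered 957 and 952 at 240 µg/ml and 2559 and 2546 at 480 µg/ml.

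**Figure D1:**
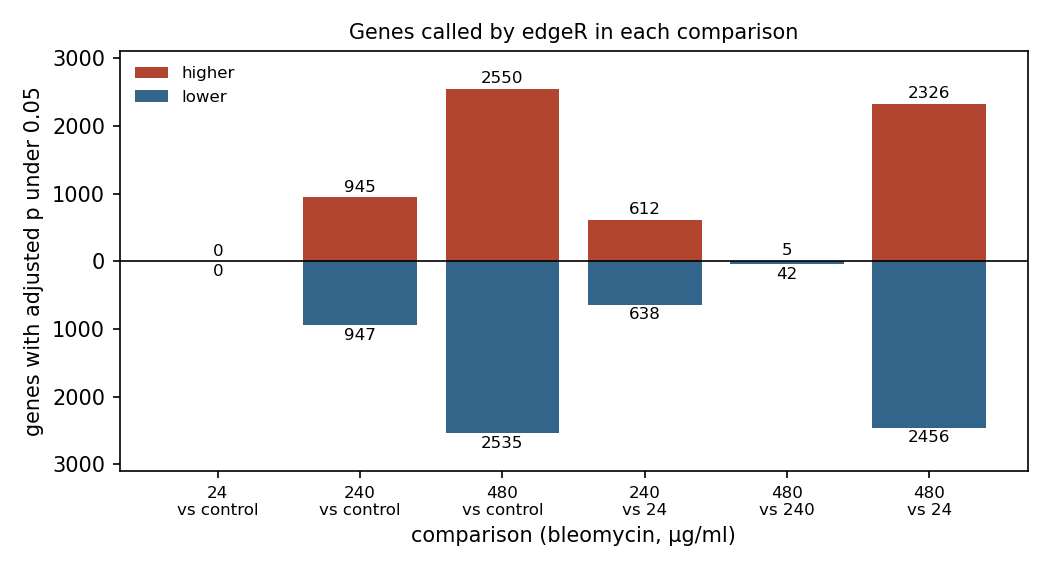
Bars give the number of genes with adjusted p under 0.05 by edgeR in each comparison of 2 groups of 2 libraries, higher above the line and lower under it. The counts were 0 and 0 at 24 µg/ml, 945 and 947 at 240 µg/ml, and 2550 and 2535 at 480 µg/ml against untreated cells. With only the 2 groups compared, which is not drawn, they were 12 and 2, 2660 and 2739, and 1308 and 1550.

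The comparison of 24 µg/ml with untreated cells asks which genes the lowest dose moved. FDXR, a p53 target that encodes a mitochondrial reductase, stood at 7.66 ± 0.0815 CPM in untreated cells and 17.9 ± 0.399 CPM at 24 µg/ml (1.23 ± 0.19, adjusted p = 0.256). CDKN1A, the p53 target that arrests the cell cycle, stood at 174 ± 21.7 CPM and 306 ± 3.10 CPM (0.82 ± 0.18, adjusted p = 0.67). GDF15, a stress cytokine gene (0.98 ± 0.17, adjusted p = 0.356), MDM2, the gene of the p53 inhibitor (0.72 ± 0.12, adjusted p = 0.356), and ACTA2, the smooth muscle actin gene (1.03 ± 0.16, adjusted p = 0.256), also lay higher without being called. By edgeR over all 8 libraries with the filter on low counts, 0 genes were called. There were 605 genes at unadjusted p under 0.05 (370 higher and 235 lower), where chance alone would give 915. That is fewer than chance gives, so the 0 calls do not show that the dose moved no gene. The spread was estimated from all 4 groups together. The SD of the log2 ratio between libraries was 0.637 at 480 µg/ml and 0.502 at 24 µg/ml. DESeq2 called 32 genes higher, of which 9 were on the list of p53 targets, and 4 lower. edgeR called 60 and 23 with no filter on low counts and 12 and 2 from the 2 groups alone, while limma on TPM called 0 and 0. Leaving out 480 µg/ml replicate 1 gave 22 genes higher and 2 lower at 24 µg/ml, and leaving out 480 µg/ml replicate 2 gave 22 and 2 as well, each with 11 p53 targets among the higher ones. FDXR, CDKN1A, GDF15, MDM2 and ACTA2 were all called by DESeq2 (adjusted p from 3.92e-06 to 0.00658), with no filter on low counts (adjusted p from 1.39e-05 to 0.00406) and from the 2 groups alone (adjusted p from 0.02 to 0.048). They were also called without 480 µg/ml replicate 1 (adjusted p from 0.00277 to 0.037) and without 480 µg/ml replicate 2 (adjusted p from 0.00289 to 0.0344), in a range of 3.92e-06 to 1 over the alternatives.

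As a group, p53 targets lay higher at 24 µg/ml: all 39 tested targets had a log2 fold change above 0, with a median of 0.41, and 24 were called when adjusted over the list alone and 0 over all genes (camera adjusted p = 4.54e-30, adjusted p = 0.0508 with an estimated correlation). By fry, the p53 list was called (adjusted p = 0.0131) and no other list was at 24 µg/ml. Of sterol and lipid synthesis genes, 24 of 25 lay below 0, with a median of -0.25 (camera adjusted p = 2.23e-09, adjusted p = 0.241 with an estimated correlation). MSMO1, an enzyme gene of cholesterol synthesis (-0.61 ± 0.15, adjusted p = 0.777), was among them. The metal response list had a median of -0.77, with 2 of 6 called lower when adjusted over the list alone (camera adjusted p = 0.000435, adjusted p = 0.486 with an estimated correlation). Other lists called lower by camera were DNA replication (median -0.13, camera adjusted p = 0.00325, adjusted p = 0.486 with an estimated correlation), type 1 cell markers (median -0.20, camera adjusted p = 0.00743, adjusted p = 0.486 with an estimated correlation) and NRF2 targets (median -0.06, camera adjusted p = 0.0103, adjusted p = 0.486 with an estimated correlation). Hepatic genes (median -0.26, camera adjusted p = 0.000694, adjusted p = 0.535 with an estimated correlation) and intestinal genes (median -0.33, camera adjusted p = 0.00325, adjusted p = 0.535 with an estimated correlation) were called lower, and genes of ciliated airway cells were called higher (median 0.30, camera adjusted p = 0.0433, adjusted p = 0.486 with an estimated correlation). The DNA replication list lost its camera call without control replicate 2 or 24 µg/ml replicate 1 (adjusted p = 0.164 and 0.325), in a range of 0.000517 to 0.639 over its alternatives. The type 1 cell list lost its camera call without control replicate 2 or 24 µg/ml replicate 1 (adjusted p = 0.0562 and 0.325), in a range of 0.000517 to 0.639 over its alternatives. The NRF2 list lost its camera call without control replicate 1 or 24 µg/ml replicate 1 (adjusted p = 0.0964 and 0.211), in a range of 0.0102 to 0.639 over its alternatives. The hepatic list lost its camera call without 24 µg/ml replicate 2 (adjusted p = 0.744), in a range of 2.16e-12 to 0.744 over its alternatives. The intestinal list lost its camera call without control replicate 1 or 24 µg/ml replicate 2 (adjusted p = 0.122 and 0.668), in a range of 2.84e-06 to 0.668 over its alternatives. The ciliated cell list lost its camera call with no filter on low counts and without control replicate 1, 24 µg/ml replicate 2 or 480 µg/ml replicate 1 (adjusted p = 0.147, 0.403, 0.0971 and 0.0669), in a range of 0.00125 to 0.639 over its alternatives. Without 24 µg/ml replicate 2 the hepatic median was 0.06, with the opposite sign.

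By edgeR over all 8 libraries with the filter on low counts, no gene tied to fibrosis or to alveolar identity was called at 24 µg/ml. The log2 fold changes of COL1A1, FN1, VIM, CDH1, KRT8 and TGFB1, which encode matrix, cytoskeletal, junction and TGF-beta pathway proteins, lay between -0.12 ± 0.18 for KRT8 and 0.29 ± 0.20 for TGFB1. SFTPB (0.42 ± 0.38, adjusted p = 1), NKX2-1 (-0.06 ± 0.44, adjusted p = 1), CXCL8, a neutrophil chemokine gene (-0.84 ± 0.62, adjusted p = 1), and MKI67, a marker of dividing cells (-0.04 ± 0.22, adjusted p = 1), lay within 2 SE of 0. INHBA, a gene of a TGF-beta family ligand, stood at 2.22 ± 0.288 CPM in untreated cells and 0.587 ± 0.0243 CPM at 24 µg/ml (-1.92 ± 0.33, adjusted p = 0.356). The type 2 cell list had a median of 0.03 over 19 genes (camera adjusted p = 0.0931), EMT and matrix genes 0.07 over 30 (camera adjusted p = 0.346) and the TGF-beta list -0.05 over 22 (camera adjusted p = 0.202), none with a gene called over all genes. Adjusted over the list alone, 2 EMT and matrix genes were higher and 1 TGF-beta gene was lower. At 24 µg/ml the median, mean and test differed in sign for the lists of histones, epithelial junction genes, interferon response, unfolded protein response and pluripotency. INHBA gained a call with no filter on low counts, by DESeq2 and without 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.000807, 0.0499, 0.0465 and 0.0436), in a range of 0.000807 to 1 over its alternatives.

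The comparison at 240 µg/ml asks the same question at the middle dose, and 945 genes rose and 947 fell against untreated cells. FDXR rose from 7.66 ± 0.0815 CPM to 46.4 ± 1.24 CPM (log2 fold change 2.60 ± 0.19, adjusted p = 0.00072). CDKN1A rose from 174 ± 21.7 CPM to 707 ± 18.3 CPM (log2 fold change 2.03 ± 0.19, adjusted p = 0.0013). FAS, a death receptor gene (2.07 ± 0.17, adjusted p = 0.000893), MDM2 (1.63 ± 0.13, adjusted p = 0.00072), TRIM22, a p53-induced antiviral gene (1.56 ± 0.14, adjusted p = 0.00106), and GDF15 (1.37 ± 0.17, adjusted p = 0.00374) rose too. Of the p53 targets, 31 of 39 rose (34 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 2.02e-21, adjusted p = 0.0963 with an estimated correlation). Outside that list, ACTA2, which overlaps FAS on the opposite strand, rose from 18.8 ± 2.38 CPM to 90.4 ± 4.89 CPM (log2 fold change 2.27 ± 0.17, adjusted p = 0.00072). PROM2, a membrane glycoprotein gene (2.55 ± 0.20, adjusted p = 0.000817), APLP1, a gene of the amyloid precursor family (2.17 ± 0.22, adjusted p = 0.00158), and SYTL1, a vesicle transport gene (2.14 ± 0.22, adjusted p = 0.00165), rose as well. GDF15 lost its call without control replicate 2 (adjusted p = 0.051), in a range of 9.42e-13 to 0.051 over its alternatives.

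Metallothionein genes, whose products bind zinc and copper, fell furthest of the named genes at 240 µg/ml. MT2A fell from 86.0 ± 6.76 CPM to 6.24 ± 3.10 CPM (log2 fold change -3.79 ± 0.38, adjusted p = 0.00158). MT1X fell from 34.2 ± 1.18 CPM to 1.22 ± 0.614 CPM (log2 fold change -4.83 ± 0.43, adjusted p = 0.00107). These are near-identical copies, so their single values are uncertain, and all 6 tested members of the metal response list fell (6 adjusted over the list alone, camera adjusted p = 2.81e-07, adjusted p = 0.152 with an estimated correlation). CP, which encodes the copper carrier ceruloplasmin, fell from 59.0 ± 4.53 CPM to 8.78 ± 2.66 CPM (log2 fold change -2.75 ± 0.26, adjusted p = 0.0013). SLC17A4, an intestinal phosphate and urate transporter gene (-2.15 ± 0.19, adjusted p = 0.00115), and CA12, a carbonic anhydrase gene (-2.0 ± 0.19, adjusted p = 0.0013), fell too.

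Most tested genes of cell division and DNA copying fell at 240 µg/ml. KIF20A, a motor protein gene of late mitosis, fell from 50.3 ± 0.758 CPM to 22.7 ± 0.379 CPM (log2 fold change -1.15 ± 0.11, adjusted p = 0.00135). UHRF1, which keeps DNA methylation through replication, fell from 23.8 ± 0.565 CPM to 6.97 ± 0.535 CPM (log2 fold change -1.77 ± 0.13, adjusted p = 0.00072). Of genes of G2 phase and mitosis, 28 of 36 fell (35 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 1.62e-19, adjusted p = 0.209 with an estimated correlation). Of DNA replication genes, 22 of 35 fell (29 adjusted over the list alone) and 1 rose (camera adjusted p = 1.16e-14, adjusted p = 0.152 with an estimated correlation). Of repair genes of homologous recombination, 8 of 20 fell (13 adjusted over the list alone, camera adjusted p = 4.47e-08, adjusted p = 0.257 with an estimated correlation). Of histone genes, 7 of 15 rose (8 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.257 with an estimated correlation). Among sterol and lipid genes, 13 of 25 fell (18 adjusted over the list alone, camera adjusted p = 6.74e-09, adjusted p = 0.152 with an estimated correlation). Of heat shock genes, 6 of 15 fell (8 adjusted over the list alone) and 0 rose (1 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.000238, adjusted p = 0.152 with an estimated correlation).

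Among hepatic genes, FGA, which encodes a fibrinogen chain, rose from 312 ± 19.9 CPM to 1292 ± 108 CPM (log2 fold change 2.05 ± 0.21, adjusted p = 0.0018), and FGB, another fibrinogen chain gene (1.31 ± 0.15, adjusted p = 0.00284), rose too. In the hepatic list 3 of 16 rose (9 adjusted over the list alone, camera adjusted p = 0.000158, adjusted p = 0.382 with an estimated correlation). In the interferon list 4 of 27 rose (9 adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.213 with an estimated correlation), including IFI6 (1.56 ± 0.17, adjusted p = 0.00247). In the secretory and inflammatory list 5 of 26 fell (9 adjusted over the list alone) and 1 rose (camera adjusted p = 0.000131, adjusted p = 0.152 with an estimated correlation). SLC34A2, the phosphate transporter gene of type 2 cells, fell from 14.7 ± 0.901 CPM to 3.09 ± 1.34 CPM (log2 fold change -2.26 ± 0.30, adjusted p = 0.00424). Of type 2 cell markers, 2 of 19 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.656). Of type 1 cell markers, 2 of 17 fell (4 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.322 with an estimated correlation), including GPRC5A, a receptor gene (-1.64 ± 0.19, adjusted p = 0.00284). TAGLN, a contractile gene that TGF-beta induces, fell from 50.2 ± 15.3 CPM to 12.9 ± 3.21 CPM (log2 fold change -1.95 ± 0.26, adjusted p = 0.00427), and in the TGF-beta list 6 of 22 fell (6 adjusted over the list alone) and 0 rose (1 adjusted over the list alone, camera adjusted p = 0.00354, adjusted p = 0.223 with an estimated correlation). Of mesenchymal genes, 0 of 13 rose and 3 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.317 with an estimated correlation). Of NRF2 targets, 1 of 22 rose and 6 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.00302, adjusted p = 0.257 with an estimated correlation). Of pluripotency genes, 0 of 7 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.0059, adjusted p = 0.322 with an estimated correlation). Of neural genes, 0 of 11 rose and 2 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.00302, adjusted p = 0.209 with an estimated correlation). The mesenchymal list lost its camera call without control replicate 2 or 240 µg/ml replicate 2 (adjusted p = 0.064 and 0.11), in a range of 0.00216 to 0.317 over its alternatives.

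MKI67 (-1.49 ± 0.23, adjusted p = 0.00779) fell at 240 µg/ml. COL1A1 (-0.12 ± 0.18, adjusted p = 0.714), VIM (0.10 ± 0.16, adjusted p = 0.741), CDH1 (-0.16 ± 0.12, adjusted p = 0.431), KRT8 (-0.28 ± 0.18, adjusted p = 0.369) and TGFB1 (0.27 ± 0.20, adjusted p = 0.439) were not called. FN1 (-0.34 ± 0.11, adjusted p = 0.0813), SFTPB (-0.49 ± 0.39, adjusted p = 0.466), NKX2-1 (-1.74 ± 0.49, adjusted p = 0.0532) and CXCL8 (-2.53 ± 0.71, adjusted p = 0.0549) were not called either. Of EMT and matrix genes, 2 of 30 rose and 7 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.137). Of genes reported in transitional and basaloid cells of fibrotic lung, 2 of 26 rose and 5 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.0763). The transitional cell list gained a camera call with no filter on low counts and without 240 µg/ml replicate 1 (adjusted p = 0.0438 and 0.0463), in a range of 0.0438 to 0.411 over its alternatives. MKI67 lost its call without control replicate 1, control replicate 2, 240 µg/ml replicate 1 or 240 µg/ml replicate 2 (adjusted p = 0.0554, 0.0645, 0.0556 and 0.0958), in a range of 4.97e-10 to 0.0958 over its alternatives. FN1 gained a call with no filter on low counts, with only the 2 groups compared and without 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.0269, 0.0344, 0.0228 and 0.0228), in a range of 0.0228 to 0.381 over its alternatives. SFTPB gained a call with only the 2 groups compared (adjusted p = 0.00818), in a range of 0.00818 to 0.751 over its alternatives. NKX2-1 gained a call with no filter on low counts, with the stricter filter, with only the 2 groups compared and without 24 µg/ml replicate 1, 24 µg/ml replicate 2, 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.00338, 0.043, 0.00739, 0.0336, 0.0388, 0.0292 and 0.0294), in a range of 0.00338 to 0.261 over its alternatives. CXCL8 gained a call with no filter on low counts, with only the 2 groups compared, by DESeq2, by limma on TPM and without 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.000148, 0.00648, 0.0136, 0.0422, 0.0106 and 0.00977), in a range of 0.000148 to 0.298 over its alternatives.

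The counts at 240 µg/ml moved with single libraries. The numbers of genes higher and lower were 68 and 85 without control replicate 1, 69 and 95 without control replicate 2, 563 and 550 without 24 µg/ml replicate 1, 565 and 566 without 24 µg/ml replicate 2, 180 and 167 without 240 µg/ml replicate 1, 70 and 50 without 240 µg/ml replicate 2, 2392 and 2576 without 480 µg/ml replicate 1 and 2438 and 2544 without 480 µg/ml replicate 2. With a library left out, the remaining library of its group is assumed to vary like the other groups. limma on TPM called 539 higher and 853 lower, so that 38.7% of its calls were higher, against 49.9% by edgeR.

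The comparison at 480 µg/ml asks what the highest dose changed, and 2550 genes rose and 2535 fell against untreated cells. The spread was pooled over all 4 groups, while the libraries of 480 µg/ml lay further apart than those of the other groups. With only the 2 groups compared, 1308 and 1550 genes were called at 480 µg/ml and 2660 and 2739 at 240 µg/ml. That reverses the order of the 2 doses, so the numbers of called genes do not rank them. CDKN1A (chromosome 6, 36676463 to 36687332 in GRCh38) rose from 174 ± 21.7 CPM to 956 ± 273 CPM (log2 fold change 2.46 ± 0.19, adjusted p = 0.000137), and FDXR (chromosome 17, 74862497 to 74872994) rose from 7.66 ± 0.0815 CPM to 63.7 ± 18.6 CPM (log2 fold change 3.06 ± 0.20, adjusted p = 0.000105). MDM2 (1.84 ± 0.13, adjusted p = 0.000107), GDF15 (1.57 ± 0.17, adjusted p = 0.000524) and FAS (2.15 ± 0.17, adjusted p = 0.000158) rose too. Of the p53 targets, 32 of 39 rose (35 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 3.1e-16, adjusted p = 0.153 with an estimated correlation). ACTA2 (chromosome 10, 88935074 to 88991337), which shares exon sequence with FAS in GENCODE release 29, rose from 18.8 ± 2.38 CPM to 95.8 ± 18.4 CPM (log2 fold change 2.35 ± 0.17, adjusted p = 0.000107). APLP1 (2.41 ± 0.22, adjusted p = 0.000271) and SYTL1 (2.39 ± 0.22, adjusted p = 0.000271) rose as well. Single libraries moved the counts, which were 956 and 1332 without control replicate 1, 954 and 1294 without control replicate 2 and 3729 and 4160 without 480 µg/ml replicate 1.

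**Figure D2:**
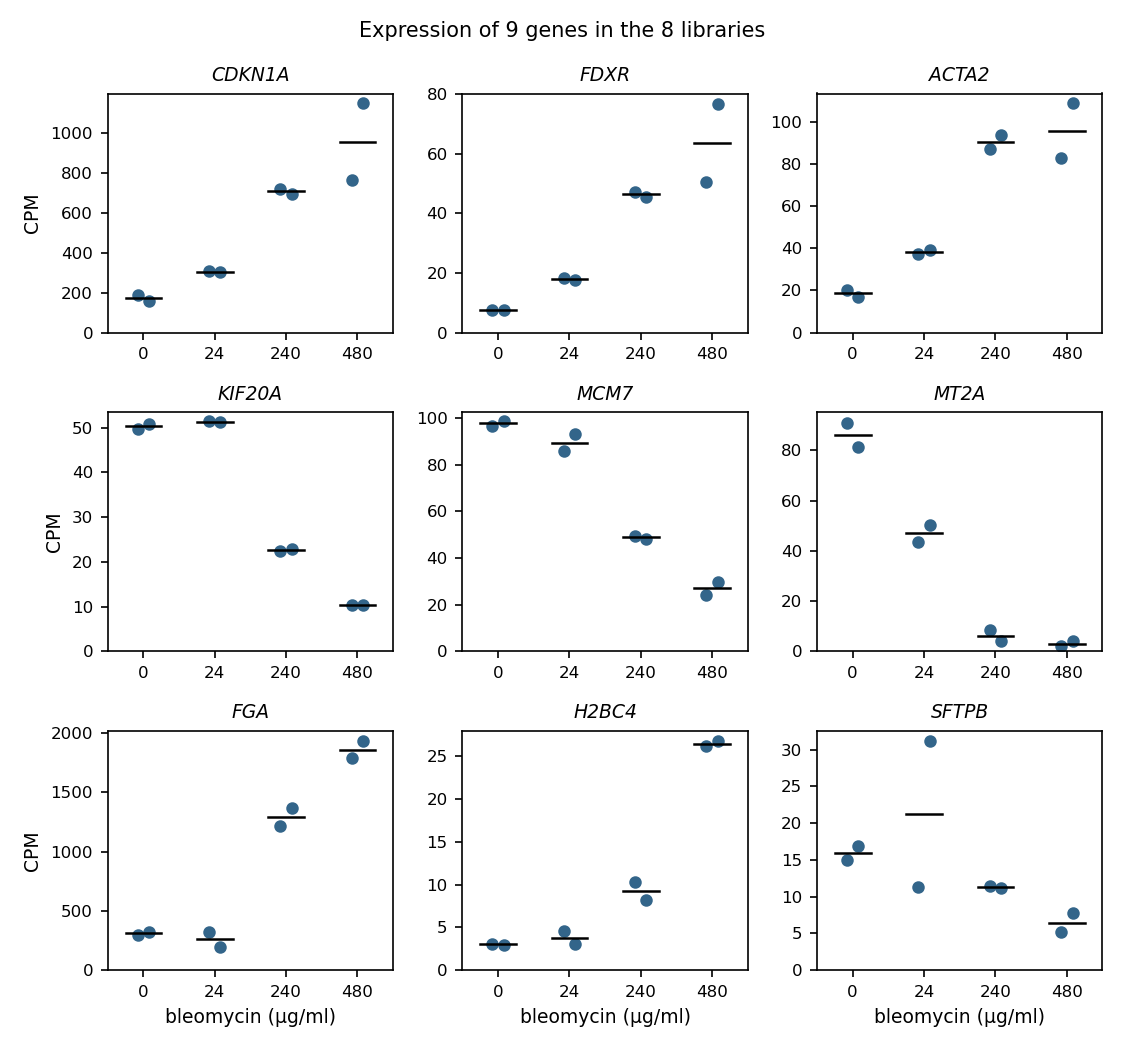
Points give the level (CPM) of 9 genes in each library against the bleomycin dose (µg/ml, equally spaced), and lines the mean of the 2 libraries. CDKN1A, FDXR and ACTA2 lie higher and KIF20A, MCM7 and MT2A lower at 240 and 480 µg/ml than in untreated cells.

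Genes of cell division fell at 480 µg/ml. KIF20A fell from 50.3 ± 0.758 CPM to 10.4 ± 0.0544 CPM (log2 fold change -2.28 ± 0.11, adjusted p = 6.18e-05). MKI67 fell from 123 ± 4.70 CPM to 25.2 ± 10.1 CPM (log2 fold change -2.28 ± 0.24, adjusted p = 0.000411). PLK1, a mitotic kinase gene (-1.84 ± 0.13, adjusted p = 0.000107), and BIRC5, which encodes survivin (-1.61 ± 0.11, adjusted p = 0.000107), fell too. All 36 tested genes of G2 phase and mitosis fell (36 adjusted over the list alone, camera adjusted p = 1.58e-21, adjusted p = 0.153 with an estimated correlation). The replicative helicase gene MCM7 fell from 97.6 ± 1.52 CPM to 26.9 ± 3.79 CPM (log2 fold change -1.86 ± 0.13, adjusted p = 0.000107), as did UHRF1 (-3.12 ± 0.14, adjusted p = 5.7e-05). Of DNA replication genes, 31 of 35 fell (31 adjusted over the list alone, camera adjusted p = 5.39e-16, adjusted p = 0.153 with an estimated correlation). The 1 that rose was TYMS, the thymidylate synthase gene (0.60 ± 0.11, adjusted p = 0.00394). Of homologous recombination genes, 18 of 20 fell (19 adjusted over the list alone, camera adjusted p = 1.8e-08, adjusted p = 0.269 with an estimated correlation), including RAD54L, a DNA translocase gene (-1.36 ± 0.14, adjusted p = 0.000363). TYMS lost its call without control replicate 1 or control replicate 2 (adjusted p = 0.0552 and 0.0518), in a range of 6.21e-05 to 0.0552 over its alternatives.

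Most tested histone genes, whose messages in dividing cells mostly carry no poly(A) tail, rose. H2BC4 rose from 3.00 ± 0.0235 CPM to 26.5 ± 0.433 CPM (log2 fold change 3.14 ± 0.21, adjusted p = 0.000107). H1-2 rose from 16.3 ± 1.25 CPM to 85.6 ± 12.2 CPM (log2 fold change 2.39 ± 0.19, adjusted p = 0.000155). Of histone genes, 9 of 15 rose (10 adjusted over the list alone), with a median of 1.46 (camera adjusted p = 2.17e-07, adjusted p = 0.153 with an estimated correlation). Many histone genes resemble one another and the handling of shared reads is not stated, so the value of each is uncertain.

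Metallothionein genes fell at 480 µg/ml too. MT2A (chromosome 16, 56608584 to 56609497) fell from 86.0 ± 6.76 CPM to 3.00 ± 1.47 CPM (log2 fold change -4.84 ± 0.40, adjusted p = 0.000185). MT1X fell from 34.2 ± 1.18 CPM to 0.386 ± 0.348 CPM (log2 fold change -6.43 ± 0.48, adjusted p = 0.000117). All 6 tested genes of the metal response list fell (6 adjusted over the list alone, camera adjusted p = 5.49e-06, adjusted p = 0.153 with an estimated correlation). CP fell from 59.0 ± 4.53 CPM to 3.60 ± 0.986 CPM (log2 fold change -4.04 ± 0.28, adjusted p = 0.000107). SLC17A4 (-3.86 ± 0.22, adjusted p = 9.24e-05), MGAM2, an intestinal glucosidase gene (-3.57 ± 0.40, adjusted p = 0.000572), LGR5, a receptor gene of Wnt-dependent stem cells (-3.41 ± 0.31, adjusted p = 0.00028), and GLP1R, the incretin receptor gene (-3.18 ± 0.24, adjusted p = 0.000112), were also among the genes that fell furthest.

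Most genes of lipid synthesis and most heat shock genes fell at 480 µg/ml. FASN, the fatty acid synthase gene (-1.51 ± 0.15, adjusted p = 0.000382), and HSP90AA1, a cytosolic chaperone gene (-0.81 ± 0.12, adjusted p = 0.00174), fell, while HSPA4L, a testis-enriched chaperone gene (1.12 ± 0.21, adjusted p = 0.00472), rose. Of sterol and lipid genes, 17 of 25 fell (18 adjusted over the list alone) and 1 rose (camera adjusted p = 1.86e-06, adjusted p = 0.153 with an estimated correlation). Of heat shock genes, 9 of 15 fell (9 adjusted over the list alone) and 1 rose (camera adjusted p = 0.00415, adjusted p = 0.153 with an estimated correlation).

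At 480 µg/ml the called genes of the secretory and inflammatory list fell, and most called interferon genes rose. IL32, a cytokine gene, fell from 25.9 ± 3.5 CPM to 5.34 ± 1.08 CPM (log2 fold change -2.28 ± 0.27, adjusted p = 0.000759). MMP1, a collagenase gene, fell from 492 ± 24.9 CPM to 201 ± 2.69 CPM (log2 fold change -1.29 ± 0.16, adjusted p = 0.000846). IGFBP3, a gene of a carrier of insulin-like growth factor (-1.57 ± 0.16, adjusted p = 0.000379), fell, and CXCL8 (-1.72 ± 0.66, adjusted p = 0.084) was not called. In the secretory and inflammatory list 12 of 26 fell (15 adjusted over the list alone), 0 rose (1 adjusted over the list alone) and the median was -1.22 (camera adjusted p = 0.000158, adjusted p = 0.153 with an estimated correlation). IFI6, an interferon-induced mitochondrial gene, rose from 1.64 ± 0.103 CPM to 8.40 ± 0.676 CPM (log2 fold change 2.36 ± 0.17, adjusted p = 0.000112), as did IFIT1, an RNA sensor gene (2.96 ± 0.32, adjusted p = 0.000473), and MX1, an antiviral gene (1.48 ± 0.18, adjusted p = 0.000806). In the interferon list 13 of 27 rose (13 adjusted over the list alone) and 2 fell (camera adjusted p = 4.14e-05, adjusted p = 0.153 with an estimated correlation). CXCL8 gained a call with no filter on low counts, by limma on TPM and without 480 µg/ml replicate 1 (adjusted p = 0.0035, 0.043 and 0.0112), in a range of 0.0035 to 0.332 over its alternatives.

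Alveolar markers moved in both directions at 480 µg/ml. ABCA3 rose from 13.1 ± 1.58 CPM to 28.9 ± 4.61 CPM (log2 fold change 1.15 ± 0.16, adjusted p = 0.00154), while SLC34A2 fell from 14.7 ± 0.901 CPM to 1.43 ± 0.194 CPM (log2 fold change -3.35 ± 0.32, adjusted p = 0.00029) and LPCAT1, a surfactant lipid enzyme gene, fell from 118 ± 2.39 CPM to 60.2 ± 0.0770 CPM (log2 fold change -0.97 ± 0.11, adjusted p = 0.000624). SFTPB fell to 6.47 ± 1.78 CPM (-1.30 ± 0.40, adjusted p = 0.0393) and NKX2-1 to 0.285 ± 0.0318 CPM (-1.68 ± 0.48, adjusted p = 0.0301). Of type 2 cell markers, 2 of 19 rose and 6 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.263, fry adjusted p = 0.0403). Of type 1 cell markers, 1 of 17 rose and 6 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.294 with an estimated correlation). Of lung progenitor genes, 1 of 19 rose and 6 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.12). The type 1 cell list lost its camera call without 480 µg/ml replicate 2 (adjusted p = 0.092), in a range of 0.000438 to 0.294 over its alternatives. The lung progenitor list gained a camera call with no filter on low counts (adjusted p = 0.0282), in a range of 0.00797 to 0.294 over its alternatives. SFTPB lost its call by DESeq2 and without control replicate 1, control replicate 2, 240 µg/ml replicate 1, 240 µg/ml replicate 2 or 480 µg/ml replicate 1 (adjusted p = 0.0533, 0.0987, 0.144, 0.0648, 0.0646 and 0.105), in a range of 8.95e-06 to 0.144 over its alternatives. NKX2-1 lost its call without control replicate 1, control replicate 2, 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.0751, 0.133, 0.0661 and 0.0576), in a range of 0.00196 to 0.133 over its alternatives.

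Most called genes of matrix, mesenchymal state and TGF-beta signalling fell at 480 µg/ml. COL3A1, which encodes a fibrillar collagen, fell from 53.3 ± 8.73 CPM to 26.1 ± 0.737 CPM (log2 fold change -1.03 ± 0.17, adjusted p = 0.00309). THBS1, which encodes an activator of TGF-beta (-1.40 ± 0.17, adjusted p = 0.000896), fell, and FN1 fell to 8247 ± 444 CPM (-0.52 ± 0.11, adjusted p = 0.0085). COL1A1 (-0.20 ± 0.18, adjusted p = 0.428), VIM (-0.22 ± 0.16, adjusted p = 0.343) and TGFB1 (0.37 ± 0.20, adjusted p = 0.205) were not called. Of EMT and matrix genes, 3 of 30 rose and 11 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.294 with an estimated correlation). Of TGF-beta response genes, 1 of 22 rose and 8 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.294 with an estimated correlation). The EMT and matrix list lost its camera call without control replicate 2, 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.0796, 0.0915 and 0.0833), in a range of 0.00443 to 0.294 over its alternatives. The TGF-beta list lost its camera call without 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.0915 and 0.0626), in a range of 0.00367 to 0.294 over its alternatives. FN1 lost its call without control replicate 2 (adjusted p = 0.073), in a range of 0.00018 to 0.073 over its alternatives. TGFB1 gained a call without 480 µg/ml replicate 1 (adjusted p = 0.00784), in a range of 0.00784 to 0.858 over its alternatives.

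Among epithelial genes at 480 µg/ml, CDH1 (-0.09 ± 0.12, adjusted p = 0.615) and KRT8 (-0.36 ± 0.19, adjusted p = 0.174) were not called. ESRP1, a splicing regulator of epithelial cells, fell from 234 ± 6.57 CPM to 120 ± 18.4 CPM (log2 fold change -0.96 ± 0.13, adjusted p = 0.00126). Of epithelial junction genes, 0 of 24 rose and 4 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.107). Of genes of transitional and basaloid cells, 4 of 26 rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.255). CDKN1A and GDF15 count among the last and among the p53 targets. TM4SF1, a membrane protein gene of the transitional list, fell from 321 ± 34.0 CPM to 50.6 ± 5.43 CPM (log2 fold change -2.67 ± 0.21, adjusted p = 0.000151). The epithelial junction list gained a camera call with no filter on low counts (adjusted p = 0.0258), in a range of 0.0258 to 0.481 over its alternatives. KRT8 gained a call with no filter on low counts and without 480 µg/ml replicate 2 (adjusted p = 0.0477 and 0.0039), in a range of 0.0039 to 0.53 over its alternatives.

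Genes of other endoderm lineages also moved at 480 µg/ml. FGA (chromosome 4, 154583126 to 154590742) rose from 312 ± 19.9 CPM to 1862 ± 99.8 CPM (log2 fold change 2.58 ± 0.22, adjusted p = 0.000195), FGB rose from 1856 ± 227 CPM to 4731 ± 90.5 CPM (log2 fold change 1.35 ± 0.15, adjusted p = 0.000586) and FGG rose from 117 ± 12.4 CPM to 442 ± 19.5 CPM (log2 fold change 1.92 ± 0.27, adjusted p = 0.0014). These 3 genes encode the chains of fibrinogen. Of hepatic genes, 5 of 16 rose (5 adjusted over the list alone) and 1 fell (camera adjusted p = 0.032, adjusted p = 0.554 with an estimated correlation). CDX2 rose from 198 ± 11.1 CPM to 389 ± 37.4 CPM (log2 fold change 0.97 ± 0.14, adjusted p = 0.00143), while the intestinal fatty acid carrier gene FABP1 fell from 188 ± 6.08 CPM to 77.0 ± 5.42 CPM (log2 fold change -1.29 ± 0.18, adjusted p = 0.00132). Of intestinal genes, 1 of 13 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.00849, adjusted p = 0.432 with an estimated correlation). The hepatic list lost its camera call without control replicate 2, 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.0565, 0.0915 and 0.086), in a range of 0.00937 to 0.554 over its alternatives. The intestinal list lost its camera call without 480 µg/ml replicate 1 (adjusted p = 0.0519), in a range of 0.00246 to 0.432 over its alternatives.

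Genes of stress pathways other than p53 moved in both directions at 480 µg/ml. FTL, which encodes the ferritin light chain, rose from 4015 ± 466 CPM to 13127 ± 3508 CPM (log2 fold change 1.71 ± 0.18, adjusted p = 0.000473). AKR1B10, an NRF2-driven aldehyde reductase gene, fell from 18.6 ± 1.99 CPM to 2.58 ± 0.50 CPM (log2 fold change -2.84 ± 0.18, adjusted p = 0.000105). Of NRF2 targets, 2 of 22 rose and 7 fell (3 and 10 adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.358 with an estimated correlation). Of unfolded protein genes, CRELD2, an endoplasmic reticulum chaperone gene (1.38 ± 0.21, adjusted p = 0.0018), rose and PSAT1, a serine synthesis gene (-1.0 ± 0.14, adjusted p = 0.00147), fell. Of unfolded protein response genes, 4 of 24 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.489). EGR1, an immediate early gene, rose from 6.97 ± 0.299 CPM to 16.4 ± 2.71 CPM (log2 fold change 1.23 ± 0.17, adjusted p = 0.00123). MYC, which drives cell growth, fell from 61.7 ± 7.62 CPM to 12.6 ± 2.69 CPM (log2 fold change -2.29 ± 0.29, adjusted p = 0.000924). Of immediate early genes, 1 of 20 rose and 3 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.872). The NRF2 list lost its camera call without 480 µg/ml replicate 1 (adjusted p = 0.228), in a range of 0.00399 to 0.358 over its alternatives.

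Genes of airway and non-epithelial cells were tested because such cultures can hold other lineages. KRT15, a basal cell keratin gene, rose from 0.440 ± 0.0123 CPM to 3.5 ± 0.258 CPM (log2 fold change 2.98 ± 0.32, adjusted p = 0.000496). MUC5AC, a gel-forming mucin gene, fell from 3.71 ± 0.0685 CPM to 0.509 ± 0.147 CPM (log2 fold change -2.86 ± 0.26, adjusted p = 0.000267). LIN28A, which marks pluripotent and early cells, fell from 33.4 ± 3.25 CPM to 3.95 ± 0.172 CPM (log2 fold change -3.08 ± 0.15, adjusted p = 5.7e-05). NES, the gene of a neural progenitor filament, fell from 50.04 ± 1.80 CPM to 11.7 ± 0.947 CPM (log2 fold change -2.10 ± 0.13, adjusted p = 0.000105). PDGFRA, a fibroblast receptor gene, fell from 32.2 ± 6.32 CPM to 10.9 ± 3.33 CPM (log2 fold change -1.56 ± 0.23, adjusted p = 0.00163). Of airway basal genes, 2 of 6 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.83). Of airway secretory genes, 0 of 10 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0644). Of ciliated cell genes, 1 of 9 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.431). Of neuroendocrine genes, 2 of 10 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.83). Of mesenchymal genes, 1 of 13 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.294 with an estimated correlation). Of endothelial genes, 1 of 11 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.974). Of pluripotency genes, 0 of 7 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.338 with an estimated correlation). Of neural genes, 0 of 11 rose and 6 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.000684, adjusted p = 0.153 with an estimated correlation). The median, mean and test differed in sign for neuroendocrine genes at 240 and 480 µg/ml and for airway basal genes at 240 µg/ml. The airway secretory list gained a camera call with no filter on low counts and without control replicate 2, 24 µg/ml replicate 1, 24 µg/ml replicate 2 or 480 µg/ml replicate 2 (adjusted p = 0.034, 0.0162, 0.0386, 0.0388 and 0.0404), in a range of 0.0162 to 0.381 over its alternatives. The mesenchymal list lost its camera call without 480 µg/ml replicate 1 or 480 µg/ml replicate 2 (adjusted p = 0.0542 and 0.086), in a range of 0.0116 to 0.294 over its alternatives. The pluripotency list lost its camera call with no filter on low counts and without 480 µg/ml replicate 2 (adjusted p = 0.0646 and 0.0837), in a range of 0.0043 to 0.338 over its alternatives.

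**Figure D3:**
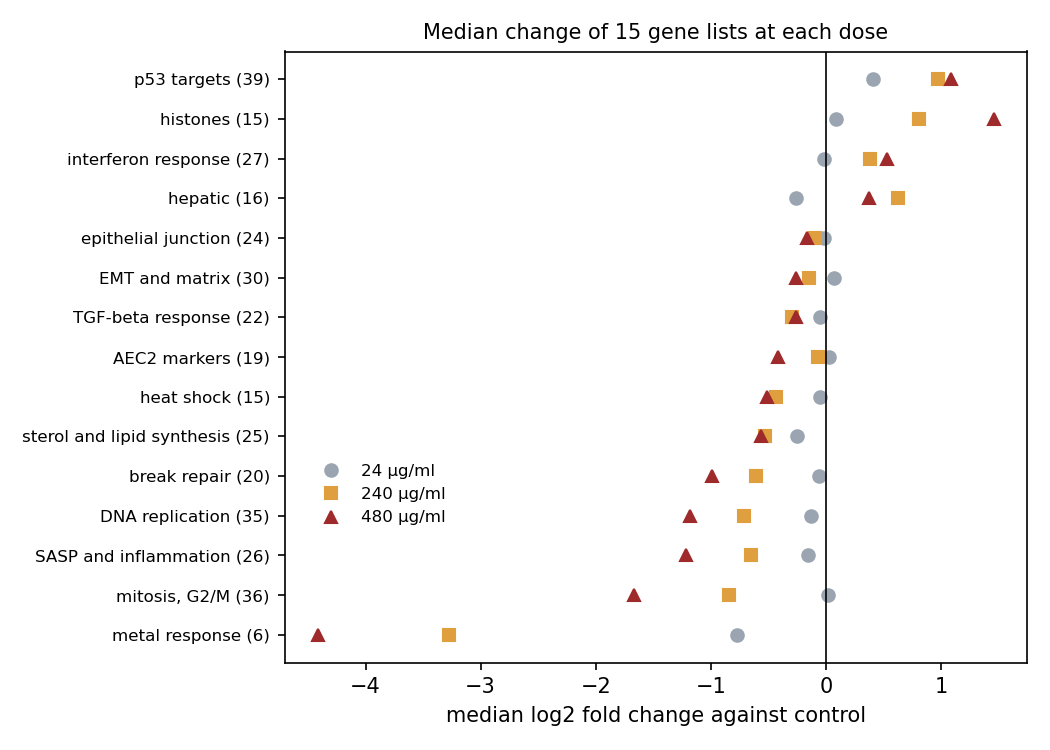
Points give the median log2 fold change against untreated cells of 15 gene lists, with the number of tested genes in parentheses, at each dose. Medians run from -4.41 for the metal response to 1.46 for histones at 480 µg/ml, and the p53 list is above 0 at each of the 3 doses.

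Differences between doses were tested directly. Between 24 and 240 µg/ml, 612 genes were higher at 240 µg/ml and 638 lower. FGA (2.31 ± 0.22, adjusted p = 0.00434) and FGG (2.41 ± 0.27, adjusted p = 0.00678) were higher at 240 than at 24 µg/ml. MT1X (-4.10 ± 0.42, adjusted p = 0.00539), CP (-2.46 ± 0.26, adjusted p = 0.00591) and LGR5 (-1.96 ± 0.28, adjusted p = 0.0114) were lower. Of p53 targets, 17 of 39 were higher (28 adjusted over the list alone, camera adjusted p = 2.13e-11, adjusted p = 0.171 with an estimated correlation), and of genes of G2 phase and mitosis, 25 of 36 were lower (35 adjusted over the list alone, camera adjusted p = 5.4e-21, adjusted p = 0.171 with an estimated correlation). Genes higher and lower numbered 191 and 218 without control replicate 1, 188 and 217 without control replicate 2, 54 and 70 without 24 µg/ml replicate 1, 5 and 11 without 24 µg/ml replicate 2, 23 and 35 without 240 µg/ml replicate 1, 0 and 0 without 240 µg/ml replicate 2, 2197 and 2413 without 480 µg/ml replicate 1 and 2210 and 2420 without 480 µg/ml replicate 2. All gene calls between these doses therefore end without 240 µg/ml replicate 2. limma on TPM called 277 and 506, with 35.4% higher, against 49% by edgeR. FGA, FGG, MT1X and CP lost their calls without 240 µg/ml replicate 2 alone (adjusted p = 0.0527, 0.0786, 0.0776 and 0.0527), in a range of 2.26e-27 to 0.0786 over their alternatives. LGR5 lost its call without 24 µg/ml replicate 2 or 240 µg/ml replicate 2 (adjusted p = 0.0968 and 0.0876), in a range of 5.04e-10 to 0.0968 over its alternatives.

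Between 240 and 480 µg/ml, 5 genes were higher at 480 µg/ml and 42 lower. H2BC4 (1.52 ± 0.20, adjusted p = 0.039), H1-2 (1.24 ± 0.18, adjusted p = 0.0402) and MFSD1, a lysosomal transporter gene (1.03 ± 0.15, adjusted p = 0.0402), were higher, as were SEMA4F, a semaphorin gene (1.55 ± 0.19, adjusted p = 0.0337), and ELOVL4, a gene of long fatty acid synthesis (1.08 ± 0.16, adjusted p = 0.0402), the last pair named after their values were seen. TM4SF4, a tetraspanin-like gene (-1.52 ± 0.15, adjusted p = 0.014), LIN28A, an RNA-binding stem cell gene (-1.40 ± 0.14, adjusted p = 0.014), GLP1R (-2.0 ± 0.23, adjusted p = 0.0311) and KIF20A (-1.13 ± 0.11, adjusted p = 0.014) were lower. Of genes of G2 phase and mitosis, 7 of 36 were lower (31 adjusted over the list alone, camera adjusted p = 4.87e-26, adjusted p = 0.244 with an estimated correlation), and of DNA replication genes, 2 of 35 (25 adjusted over the list alone, camera adjusted p = 9.52e-18, adjusted p = 0.244 with an estimated correlation). With 1 library left out the numbers higher and lower were 0 and 0 without control replicate 1, 0 and 0 without control replicate 2, 1 and 7 without 24 µg/ml replicate 1, 0 and 0 without 24 µg/ml replicate 2, 0 and 0 without 240 µg/ml replicate 1, 0 and 0 without 240 µg/ml replicate 2, 397 and 1033 without 480 µg/ml replicate 1 and 615 and 856 without 480 µg/ml replicate 2, so each call between these doses ends without at least 5 of the libraries. edgeR on the 4 libraries of these 2 groups called 0 and 0, and DESeq2 called 38 higher and 282 lower. limma on TPM called 3 and 8, with 27.3% higher, against 10.6% by edgeR.

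Between 24 and 480 µg/ml, 2326 genes were higher at 480 µg/ml and 2456 lower. BCAP29, an endoplasmic reticulum protein gene (2.44 ± 0.35, adjusted p = 0.00191), FGA (2.84 ± 0.22, adjusted p = 0.000229) and H2BC4 (2.82 ± 0.21, adjusted p = 0.000189) were higher, and MT1X (-5.71 ± 0.48, adjusted p = 0.000273), CP (-3.75 ± 0.28, adjusted p = 0.000189), LGR5 (-3.73 ± 0.31, adjusted p = 0.000275) and MGAM2 (-3.67 ± 0.40, adjusted p = 0.000692) were lower. Of p53 targets, 28 of 39 were higher (28 adjusted over the list alone, camera adjusted p = 4.4e-09, adjusted p = 0.162 with an estimated correlation). The counts that single libraries moved were 932 and 1301 without 24 µg/ml replicate 1, 800 and 1224 without 24 µg/ml replicate 2 and 3544 and 4047 without 480 µg/ml replicate 1.

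Genes called at 240 µg/ml were mostly called at 480 µg/ml. Of the 945 and 947 genes that rose and fell at 240 µg/ml, 882 and 914 did the same at 480 µg/ml, and 0 moved the opposite way by edgeR. Independent lists of these sizes would share 132 and 131, and 20 simulated pairs of unchanged groups set against the same controls shared 0 and 0. The simulated data held no effect, so few genes could be called at either dose. The 0 and 0 therefore cannot show how much sharing the shared controls give among called genes. The 2 controls are too few to give each dose 2 controls of its own, so part of the excess of shared genes may come from the shared controls. At adjusted p under 0.01, 182 and 173 genes were shared. Across genes, which are not independent replicates, the log2 fold changes at 240 and 480 µg/ml had a correlation of 0.811 (simulated 0.506) and a covariance of 0.643 (simulated 0.0689). Between 24 and 240 µg/ml the covariance was 0.222 (simulated 0.0689) and the correlation 0.521 (simulated 0.513). Between 24 and 480 µg/ml they were 0.235 (simulated 0.0694) and 0.443 (simulated 0.515). Over all genes, 85.4% had the same sign at 240 and 480 µg/ml (simulated 66.7%), 60.7% at 24 and 240 µg/ml (simulated 66.8%) and 58.0% at 24 and 480 µg/ml (simulated 66.9%).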

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

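RLE factors, the stricter filter and the fit without ribosomal RNA, mitochondrial and AFP counts, the last chosen after the data were seen, left each count of called genes within 1.5 times its value. With no filter on low counts the genes higher and lower were 60 and 23 for 24 µg/ml, 1417 and 1490 for 240 µg/ml, 1049 and 1326 for 240 against 24 and 85 and 380 for 480 against 240. DESeq2 gave 32 and 4 for 24 µg/ml, 822 and 1040 for 240 against 24 and 38 and 282 for 480 against 240, and limma on TPM gave 539 and 853 for 240 µg/ml, 277 and 506 for 240 against 24 and 3 and 8 for 480 against 240. With only the 2 groups compared they were 12 and 2 for 24 µg/ml, 2660 and 2739 for 240 µg/ml, 1308 and 1550 for 480 µg/ml, 2081 and 2260 for 240 against 24, 0 and 0 for 480 against 240 and 1075 and 1367 for 480 against 24. With replicate number as a block they were 628 and 661 for 240 µg/ml and 279 and 342 for 240 against 24. For 480 against 240 that block gave 0 and 8, and CXCL8 was called at 240 and 480 µg/ml (adjusted p = 0.041 and 0.045). The replicate 1 minus replicate 2 differences of groups had correlations between -0.08 and 0.045 across genes. These show no pairing of libraries by number, but cannot exclude a shared day or culture, which the labels do not state. At adjusted p under 0.01 the doses 240 and 480 µg/ml shared 182 genes higher and 173 lower. For the counts that moved, the cause was not tested. With each library left out in turn, genes numbered 0 to 22 higher and 0 to 2 lower for 24 µg/ml, 68 to 2438 higher and 50 to 2576 lower for 240 µg/ml, 954 to 3729 higher and 1294 to 4160 lower for 480 µg/ml, 0 to 2210 higher and 0 to 2420 lower for 240 against 24, 0 to 615 higher and 0 to 1033 lower for 480 against 240 and 800 to 3544 higher and 1224 to 4047 lower for 480 against 24. Of the 24 genes named as called at 240 µg/ml, DESeq2 kept 24 and limma on TPM 24, and of 61 at 480 µg/ml they kept 60 and 61. The naming rule favours large changes and small p, so this says little about the other calls. Of all 945 and 947 genes called higher and lower at 240 µg/ml, DESeq2 shared 855 and 903 and limma on TPM 485 and 652. Of the 9 named between 240 and 480 µg/ml, DESeq2 kept 9 and limma on TPM 2. RLE factors kept all list calls, no filter added 13 and ended 3, fry added 12 and ended 20, and the estimated correlation ended all 88. Leaving out 1 library at a time, at least 1 of the 8 fits ended 27 of the 88 list calls, added 22 others and reversed 1: the hepatic median at 24 µg/ml, -0.26 over all libraries, was 0.0617 without 24 µg/ml replicate 2 and -0.687 without 24 µg/ml replicate 1, and the cause was not tested. Depth limits genes near the floor of 3 counts, such as SFTPC.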

Other observations

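The tests of contractile genes, of FAS reads, of p53, of hepatic genes, of acute-phase genes at 240 µg/ml and of metallothionein copies below were chosen after the result was seen. The tests of acute-phase genes at 480 µg/ml, of SLC39A10 and of transcript length were set before their results were seen, and each pattern was found on the same libraries that test it.

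ACTA2 rose at 240 and 480 µg/ml (2.35 ± 0.17, adjusted p = 0.000107 at 480 µg/ml) and had 1.03 ± 0.16 at 24 µg/ml. A smooth muscle or myofibroblast-like programme in the culture as a whole is argued against by TAGLN, CNN1, MYL9, TPM1 and TPM2. These are genes of the same contractile programme, and all 5 fell at 480 µg/ml (median -0.676). The values are of whole cultures, in which most called mesenchymal genes also fell. A programme in only some of the cells therefore stays open. Reads of FAS counted to ACTA2 stay open. The 2 genes share 380 exon bases in GENCODE release 29, where FAS starts at 88990582, while RefSeq starts it at 88964050, further inside ACTA2. All FAS counts at 480 µg/ml equal 29.5% of the ACTA2 rise, but FAS reads in shared bases may be missing from them, so they bound the explanation only if reads spread evenly over FAS. The rise of ACTA2 in CPM was 4.17, 4.37 and 4.37 times that of FAS at 24, 240 and 480 µg/ml, the highest 1.048 times the lowest, as such reads or a shared response would give. A p53 response shared with FAS stays open, since the smallest ACTA2 change over the 3 doses was 1.028 while the p53 list was above 0 at each, but both follow the dose of the same drug and cannot be told apart from any other effect of dose.

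FGA, FGB and FGG rose at 240 and 480 µg/ml, up to 2.58 ± 0.22, adjusted p = 0.000195 for FGA at 480 µg/ml. A larger share of hepatic-lineage cells, as the whole rise, would lift other hepatic genes about as far. The 9 compared did not rise as far, but the 3 had been picked for their rise in these libraries. Part of the gap is thus built in, and the comparison gives no verdict. The median of the 3 exceeded that of AFP, ALB, APOA1, APOB, SERPINA1, TTR, AMBP, APOA2 and APOC3 by 1.725 on the log2 scale at 480 µg/ml (SD of these 9 genes 0.665) and by 1.366 at 240 µg/ml (SD 0.34). A larger share of hepatic-lineage cells stays open as part of the rise. At 240 µg/ml 8 of the 9 lay above 0 (median 0.516, 0 called by edgeR), while at 480 µg/ml 2 were called higher (TTR and APOA2) and 1 lower (APOC3). A general acute-phase response is argued against only for the other acute-phase genes that passed the filter on low counts. The 7 tested had a median of -0.004 (SD 0.763) at 480 µg/ml, with 1 gene called higher (ITIH4) and 1 lower (C3). CRP, SAA1, SAA2, SAA4, LBP and HAMP were listed too but did not pass the filter, so they give no evidence. At 240 µg/ml their median was 0.202 (SD 0.526), with 4 above 0, 0 called higher and 1 lower (C3). The 3 above 1 CPM, SERPINA3, SOCS3 and C3, had medians of -0.008 at 240 µg/ml and -0.004 at 480 µg/ml. HP, ORM1, ORM2 and ITIH4 lay lower and had SE of 0.437 to 0.747 at 480 µg/ml, so the argument rests mostly on those 3. CP, whose fall had been seen, was left out of these genes. A change of fibrinogen transcription or stability within the same cells may remain, and it was not tested.

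Metallothionein counts summed over 15 symbols were 153 ± 8.34 CPM in untreated cells, 85.6 ± 7.26 at 24 µg/ml, 11.2 ± 5.08 at 240 µg/ml and 4.87 ± 2.55 at 480 µg/ml. Reads moving among near-identical copies are argued against, since the sum at 480 µg/ml was 3.186% of that in untreated cells and all 5 tested copies fell. A general loss of short transcripts is argued against, since the 200 genes nearest in length had a median of 0.169. Less metal available to the sensor MTF1 stays open: SLC39A10, a zinc importer gene that MTF1 represses, had -0.224 ± 0.195 at 480 µg/ml (adjusted p = 0.421), past the bound set against this explanation. It passed the bound by less than its SE, and a margin of that size was asked for only after its value was seen. It had -0.5981 (adjusted p = 0.00265) without 480 µg/ml replicate 1, a called fall that goes against the explanation, and 0.0651 (adjusted p = 0.686) without 480 µg/ml replicate 2, in a range of 0.00265 to 0.748 over its alternatives. The 2 libraries of that dose thus disagree on it. SLC30A1, a zinc exporter gene that MTF1 induces (-0.87 ± 0.16, adjusted p = 0.00433), named after its value was seen, fell.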
